A study of Mus musculus with 6 samples.

How the data were processed

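The data are peak lists from CUT&RUN, an assay in which an antibody, here against estrogen receptor alpha (ERα, the product of Esr1), tethers micrococcal nuclease to chromatin in isolated nuclei. The nuclease cuts around the bound protein, and the released short fragments are sequenced. The nuclei came from limbic brain tissue of adult C57/BL6 male mice, per the labels. The males were gonadectomized at 10 to 12 weeks of age to remove circulating hormone. After 3 weeks they received a subcutaneous injection of 5 µg estradiol benzoate, an esterified form of estradiol, or of corn oil vehicle, and nuclei were isolated 4 hours later. There were 3 vehicle and 3 estradiol libraries, each with 1 peak list. The labels do not say whether the libraries of a group came from separate animals. The exact permutation tests of values per library therefore measure the spread between these libraries, which may be technical. Fisher's exact tests count regions, and the tests with random lists or random regions draw genes or regions, so these do not measure that spread.

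The authors' upstream steps are known in part. The submitters' processing notes name cutadapt, Bowtie2, Picard, SAMtools, deepTools and MACS2 without versions or roles, and the mouse build mm10. The names given to peaks inside the deposited lists carry a q-value of 0.01 and the number 25, whose meaning is not given in the sources used here. Each list was made from a single library, judged by those names, and whether a control library entered the peak calls is not given in the sources used here. Replicates 1 and 2 of both groups share one style of peak name, and replicate 3 of both groups has another style. Its labels are also shorter: the tissue tag reads brain, with limbic system as the source name, and the group comes from the sample title. Replicate 3 was therefore treated as a separate batch, with 1 library per group.

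The deposited lists give for each peak an integer score, which equals 10 times the −log10 q-value rounded down. They also give a fold enrichment at the summit over the caller's background, a −log10 p-value, a −log10 q-value and the summit position. These values are the authors' own, and were used here to describe, rank or filter peaks within a list, not to test a change in height between lists. The smallest −log10 q in each list was 2.00 to 2.01, which is the threshold in the peak names.

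The number of fragments behind each peak was worked out from the deposited fold and p-value. With a pseudocount of 1 in the fold and a Poisson upper tail, the way the caller computes these values by default, a whole number of summit fragments matched the −log10 p within 0.0002 for 100% of peaks in each library. The background values then fell on equally spaced steps, from which a mean fragment length of 73.5 to 79.4 bp and a background depth of 14.1 to 22.7 fragments per 10 kb followed. These are estimates that rest on the assumed formula, not values the authors state. In each library the smallest called summit held 4 fragments and the median 6, so most peaks stand on few fragments and the lack of a peak in a list is not evidence of no binding. Intervals on shares are exact 95% binomial intervals and cover counting error only.

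Overlapping or touching peaks (1 bp) of the 6 lists were merged into regions, and a library held a region if at least 1 of its peaks lay in it. Estradiol-only regions had a peak in 3 of 3 estradiol libraries and in 0 of 3 vehicle libraries, and vehicle-only regions the reverse. A single region cannot pass a test with 3 libraries against 3 (the smallest exact p is 0.1), so counts of regions were compared with those of the other splits of the 6 libraries (10 splits). Group means were compared by two-sided exact permutation tests, shares of regions by two-sided Fisher's exact tests. Regions are not independent replicates, and those Fisher tests describe the regions of these libraries.

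Genes came from a RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10, with 21887 protein-coding genes on the assembled chromosomes. The table gives the span of each gene without strand or exons. The planned distance to a transcription start site was therefore replaced by the distance to the nearest gene span, up to 500 kb, and the planned promoter share by the share of regions within 1000 bp of either end of a gene. Background for that share came from windows of the same width shifted by 5 kb to each side. Strand, exon and intron structure and genome sequence were not used here, so the planned estrogen response element counts were not run.

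The gene lists, the rule for named regions, the main tests and the alternative settings not marked as added were chosen before the data were examined; the tests of explanations, apart from the count over other splits, were chosen afterwards. Of 244 names over 17 lists, 243 matched the table and 1 did not (Asip, in the melanocortin list). The number of list genes with an estradiol-only region was compared with 10000 random lists matched on the decile of the genomic territory of each gene, one-sided, with Benjamini-Hochberg adjustment over the 17 lists. Regions were ranked by their mean within-library percentile of −log10 q. The named regions are the top 15 estradiol-only, the top 5 vehicle-only and the top 5 in all 6 libraries. List genes with an estradiol-only region are named, up to 4 per list, and Mc4r, Pgr, Greb1 and Esr1 are always described. Among these, 1 region found in all 6 libraries and the coregulator list are not reported here.

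On simulated lists in which 200 regions had been planted in the 3 estradiol libraries among 39574 regions, 100% of the planted regions were found. The planted regions met the rule by construction, so this checks merging and counting, not the sensitivity for real peaks. With libraries assigned at random to the other regions, in proportion to list length, 162 of them also met the rule, so part of any such count is made by chance. Of 2000 simulated peaks, 100% returned the fragment number they were made with. Of 500 random gene lists with no effect, 1.80% had p under 0.05 in the list test, and of 100 lists of 20 genes with 5 planted genes, 100% did. Alternatives covered a stricter q threshold, lists of equal length, other rules for presence and merging, other distances, the replicate number as a block, and each library left out in turn. Thresholds of −log10 q of 5, 7 and 10, with and without vehicle replicate 1, were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.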

Results

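ERα occupancy was profiled by CUT&RUN in limbic brain tissue of gonadectomized male mice, 4 hours after estradiol benzoate (3 libraries) or vehicle (3 libraries). The series sets out to locate ERα binding that follows estrogen, and its title concerns melanocortin neurons. The vehicle lists held 5421, 13717 and 20541 peaks and the estradiol lists 11082, 14123 and 17558. Estimated background depth was 22.0, 17.6 and 21.8 fragments per 10 kb in the vehicle libraries and 16.5, 14.1 and 22.7 in the estradiol libraries. Merging the 6 lists gave 39374 regions on mm10, of which 23183 (58.9%) were found in 1 library and 2863 (7.27%) in all 6.

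The first question was where peaks appeared in every estradiol library and in no vehicle library. There were 290 such regions, and those with the highest peaks lay near Fgf12, inside Greb1 and Dpp6, and in several stretches far from any gene. At the other end of the comparison, 44 regions were present in every vehicle library and in no estradiol library. The most highly ranked estradiol-only region, on chromosome 16 at 28089439 to 28089838, lay 67.9 kb from Fgf12, a fibroblast growth factor homologous factor that modulates voltage-gated sodium channels. Its −log10 q was 26.4, 34.7 and 62.8 in estradiol replicates 1, 2 and 3, from 25, 32 and 52 fragments at the summit.

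Greb1, a gene known for its induction by estrogen in breast and uterus, held 2 estradiol-only regions inside its span (chromosome 12, 16670615 to 16801394). The stronger one, at 16760333 to 16760598, had −log10 q of 16.5, 17.3 and 45.9 and a fold enrichment of 12.0, 12.2 and 21.2 in estradiol replicates 1, 2 and 3. The weaker one, at 16719075 to 16719120, had −log10 q of 2.56, 4.88 and 2.35, from 4, 5 and 4 summit fragments. A further Greb1 region at 16805695 to 16805774, 4.30 kb beyond the gene, had peaks in all 3 vehicle libraries and in estradiol replicate 2. Pgr, the progesterone receptor gene (chromosome 9, 8898900 to 8968611), also had 2 estradiol-only regions. The region at 8970444 to 8970549, 1.83 kb beyond the gene, had −log10 q of 3.91, 6.86 and 6.63, from 5, 7 and 8 summit fragments. The region at 8837777 to 8838022, 60.9 kb away on the other side, had −log10 q of 2.18, 4.92 and 4.36, from 4, 6 and 7. Like the weaker Greb1 region, both Pgr regions held few fragments, where the smallest called summit held 4. Over all regions assigned to Pgr, the estradiol libraries held peaks in 3, 5 and 4 of them and the vehicle libraries in 0, 1 and 0.

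**Figure D1:**
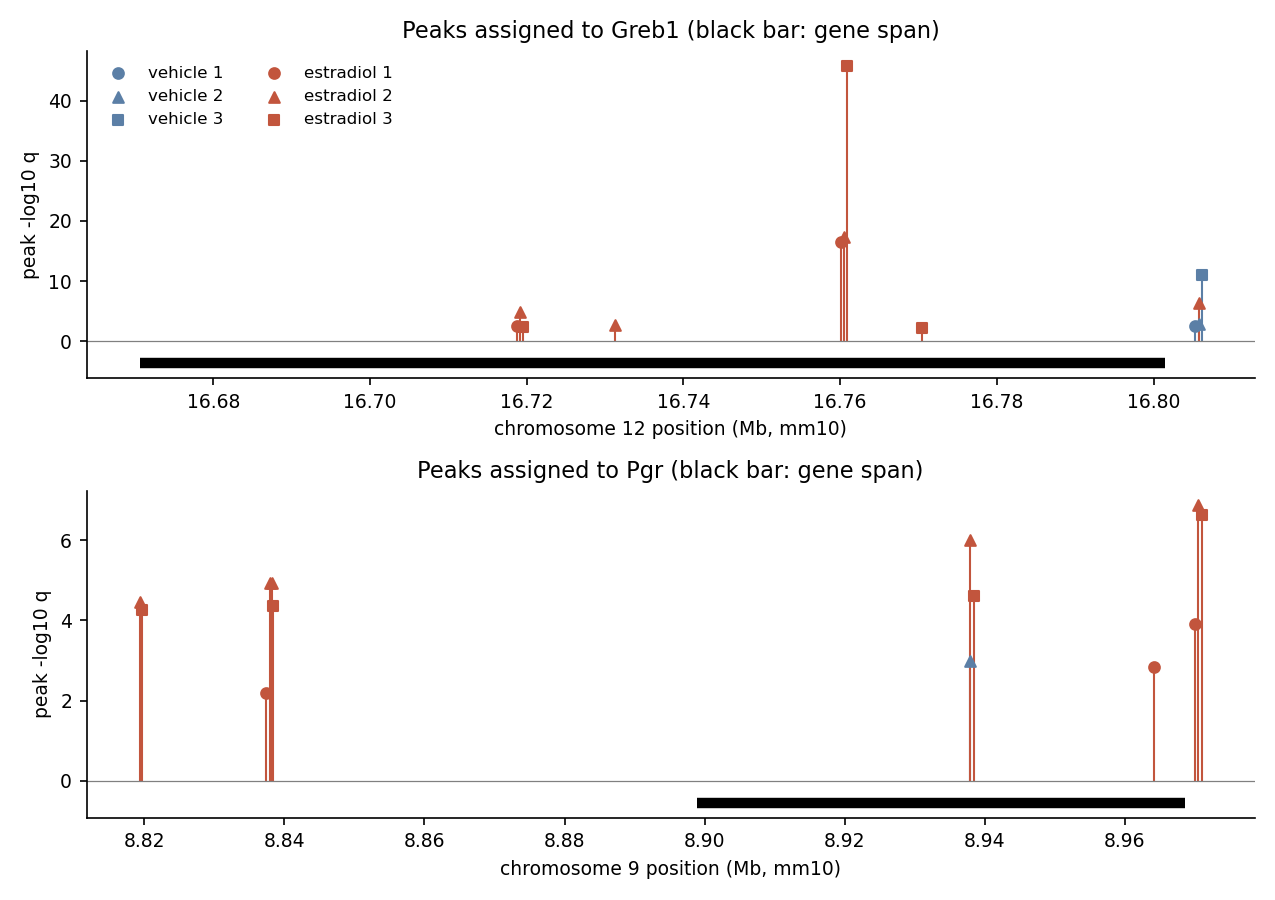
Peaks assigned to Greb1 and Pgr in the 6 libraries, with position on mm10 (Mb) on the horizontal axis and the authors' −log10 q per peak on the vertical axis. Colours mark the group and symbols the replicate, points of one region are set slightly apart sideways, and the tall peak inside Greb1 reaches 45.9 in estradiol replicate 3 with no vehicle peak beside it.

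Among the other top-ranked estradiol-only regions, 5 lay inside a gene. They were found in Dpp6, an auxiliary subunit of A-type potassium channels (chromosome 5, 27568346 to 27568587), in Oxct1, a mitochondrial enzyme of ketone body use (chromosome 15, 4078093 to 4078335), and in Zfp277, Lekr1 and 4930579F01Rik. The Dpp6 region had −log10 q of 21.6, 23.6 and 36.4, and the Oxct1 region 11.5, 20.4 and 19.0. Regions outside genes lay 5.88 kb from Pdzrn4, 11.7 kb from Col25a1, 17.1 kb from Rcn1, 28.1 kb from Fam124a, 303 kb from Sel1l and 463 kb from 4930591A17Rik. For 2 others the nearest gene was farther than 500 kb, at 541 kb (Aadat) and 814 kb (Vrk2). The Col25a1 region, at 130168597 to 130168685 on chromosome 3, had −log10 q of 23.8, 22.5 and 25.8 from 18, 19 and 21 fragments.

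The top vehicle-only regions had lower peaks, with 5 to 10 summit fragments in each vehicle library. The genes assigned to them were Kcnh8 and Kcnb2, which encode voltage-gated potassium channels, Mast4, Col6a1 and Stag3, a meiotic cohesin subunit. The Kcnh8 region (chromosome 17, 52560066 to 52560174, 42.5 kb from the gene) had −log10 q of 9.10, 5.30 and 5.58 in vehicle replicates 1, 2 and 3. Median rank within a library was at the 53.6 percentile for estradiol-only and the 39.1 percentile for vehicle-only regions.

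With 10 possible splits of the 6 libraries, neither count can reach a share under 0.1. Neither was the highest of its 10: 5 gave at least 290 regions (up to 616) and 2 gave at least 44 (up to 52), the real one included. The excess of 290 over 44 turned without vehicle replicate 1, the shortest list, to 303 estradiol-only against 876 vehicle-only regions, with the rule then applied to 2 vehicle libraries. Within replicates 1 and 2 the counts were 1060 estradiol-only and 202 vehicle-only regions, and in replicate 3, with 1 library per group, 7848 and 10851. At a −log10 q of at least 10 in each library holding the region, a threshold chosen after seeing the data, there were 14 estradiol-only and 0 vehicle-only regions. The counts were 14 and 0 without vehicle replicate 1 as well, although leaving out a vehicle library cannot lower the estradiol-only count. At that threshold replicates 1 and 2 gave 17 and 0, and replicate 3 gave 176 and 233. At a threshold of 5 there were 64 estradiol-only against 1 vehicle-only region, which turned to 64 against 75 without vehicle replicate 1. At a threshold of 7 there were 33 against 0, and 33 against 10 without it.

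**Figure D2:**
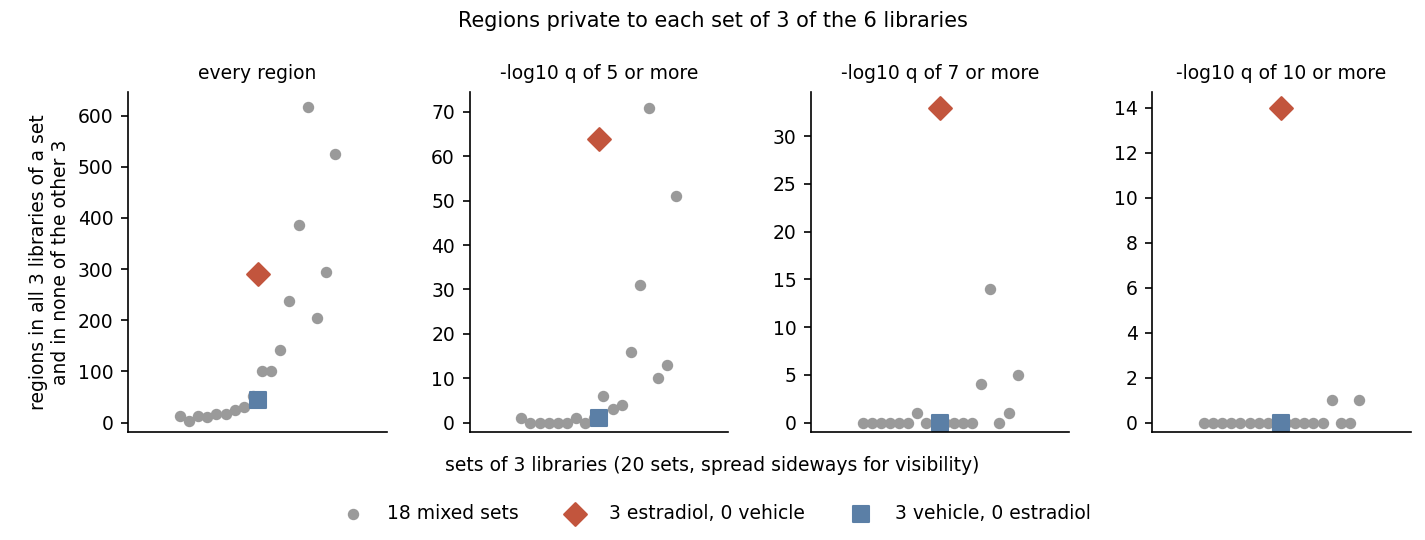
Number of merged regions with a peak in all 3 libraries of a set and in none of the other 3, for the 20 sets of 3 of the 6 libraries, in 4 panels by the least −log10 q required in each library. Diamonds mark the 3 estradiol libraries (290, 64, 33 and 14 regions), squares the 3 vehicle libraries (44, 1, 0 and 0), and circles the 18 mixed sets, whose highest counts were 616, 71, 14 and 1.

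The next question was which of the fixed gene groups had estradiol-only regions. Among 24 genes induced by estrogen in other tissues, 3 had such a region (Greb1, Myc and Pgr), against 0.509 expected from random lists (one-sided permutation p = 0.0125, adjusted p = 0.212). The region assigned to Myc, a growth-promoting transcription factor, lay 305 kb away and that of Trh, which encodes thyrotropin-releasing hormone, 49.5 kb away. Of 23 synaptic and ion channel genes, 3 had a region: Grin2b, an NMDA receptor subunit, and Cntnap2 held theirs inside the gene, and Scn2a, a sodium channel, had its region 4.33 kb away (permutation p = 0.0828, adjusted p = 0.704). Single members were found in the lists of neuropeptides (Trh, 1 of 28), hormone receptors (Pgr, 1 of 20), ventromedial hypothalamic neurons (Pgr, 1 of 15) and genes of liver, heart and pancreas (Apob, 1 of 16). No member of the immediate early (0 of 15) or circadian clock (0 of 15) lists had one. In these random-list tests 0 of 17 lists passed after Benjamini-Hochberg adjustment, and 1 had an unadjusted p under 0.05.

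Among cell type markers, Meis2 of the GABAergic neuron list (1 of 10) had an estradiol-only region, 240.0 kb from the gene. None was assigned to markers of astrocytes (0 of 8), oligodendrocytes (0 of 9), microglia (0 of 7), endothelium (0 of 6), glutamatergic neurons (0 of 8) or ependyma and choroid plexus (0 of 5). Random lists of those sizes gave at most 0.236 genes on average, so these lists are too short to show a lack.

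No estradiol-only region was assigned to Mc4r, the melanocortin 4 receptor gene, or to any of the 16 matched genes of the melanocortin and energy balance list (0.437 expected from random lists). With so few expected, the test cannot show a lack. When 2 of 3 estradiol libraries and no vehicle library sufficed, 2 of 16 had a region (Npy2r and Ntrk2), against 1.78 from random lists (permutation p = 0.556, adjusted p = 0.924). Both genes also had a region in all 6 libraries. At Mc4r (chromosome 18, 66857705 to 66860487) there were 2 regions, both at the gene's end of higher coordinates. The region at 66860526 to 66860612 had a peak in estradiol replicate 1 (−log10 q 5.37, 6 fragments) and in vehicle replicate 3 (3.24, 5 fragments). The region at 66860471 to 66860501 had a peak in vehicle replicate 2 (4.07, 5 fragments). The 1 bp merging rule kept these neighbours apart, and merging within 500 bp would join them. Joined, they would hold peaks of vehicle replicates 2 and 3 and estradiol replicate 1. Esr1 itself had 1 region, found in vehicle replicate 2 with 4 fragments. These peaks held 4 to 6 fragments, close to the smallest that was called, and the groups were not tested at single genes.

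Regions found in all 6 libraries had far higher peaks and mostly lay at gene ends. Of the top 5, 4 lay at Cdc25c and Top2a, which act in cell division, Zmynd8, a chromatin reader, and Tmem218. The Zmynd8 region lay inside its gene, farther than 1 kb from either end. The Cdc25c region (chromosome 18, 34751530 to 34751766) had 84, 134 and 208 summit fragments in the vehicle libraries and 93, 119 and 199 in the estradiol libraries. The Top2a region (chromosome 11, 99024186 to 99024448) had 75, 128 and 214 against 105, 100 and 227. These peaks were thus present without injected hormone. Whether they mark ERα binding was not tested, as no control library or genome sequence was used here.

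The position of regions relative to genes differed between these classes. Within 1 kb of either end of a protein-coding gene lay 40 of 290 estradiol-only regions (13.8%, 95% interval 10.0 to 18.3) and 2061 of 2863 regions found in all 6 libraries (72.0%, 70.3 to 73.6). Fisher's exact test gave p = 8.85e-86, and windows 5 kb to each side lay near gene ends in 3.45% and 10.3%. The 23183 regions found in 1 library had a share of 12.8%, close to that of estradiol-only regions (Fisher's exact p = 0.596). The single-library share was lower than the estradiol-only share without vehicle replicate 3 (14.3% against 32.5%, Fisher's exact p = 2.08e-30), with 50% cover (14.6% against 30.6%, p = 9.09e-07) and without vehicle replicate 2 (13.7% against 20.4%, p = 0.000280). With lists of equal length the estradiol-only share was 27.4%, and in each of these settings it was below that of regions in all the libraries used. The vehicle-only share was 27.3% (12 of 44, 15.0 to 42.8), with p = 0.0415 against estradiol-only regions in Fisher's exact test. That difference turned without vehicle replicate 3 (32.5% estradiol-only, 18.9% vehicle-only, Fisher's exact p = 0.0102) and with 50% cover (30.6% and 28.1%, Fisher's exact p = 0.835). It did not pass Fisher's exact test with lists of equal length (27.4% and 45.2%, p = 0.0523), at the stricter threshold (12.9% and 21.4%, p = 0.243) or without vehicle replicate 2 (20.4% and 24.1%, p = 0.402). The estradiol-only share stayed lower when 2 of 3 libraries sufficed (14.5% and 22.5%, Fisher's exact p = 5.05e-07). The same held without vehicle replicate 1 (15.2% and 22.7%, Fisher's exact p = 0.00517). It was also lower without estradiol replicate 1, 2 or 3 (Fisher's exact p = 0.0209, 2.27e-06 and 7.56e-05). A further 115 estradiol-only regions (39.7%) lay inside genes away from their ends and 135 (46.6%) outside genes. Per library, 41.6% ± 7.66 (SD, n = 3) of vehicle peaks and 38.9% ± 5.19 (SD, n = 3) of estradiol peaks lay near gene ends (exact permutation p = 0.7), with differences of -3.15 percentage points within replicates 1 and 2 and -1.89 in replicate 3.

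**Figure D3:**
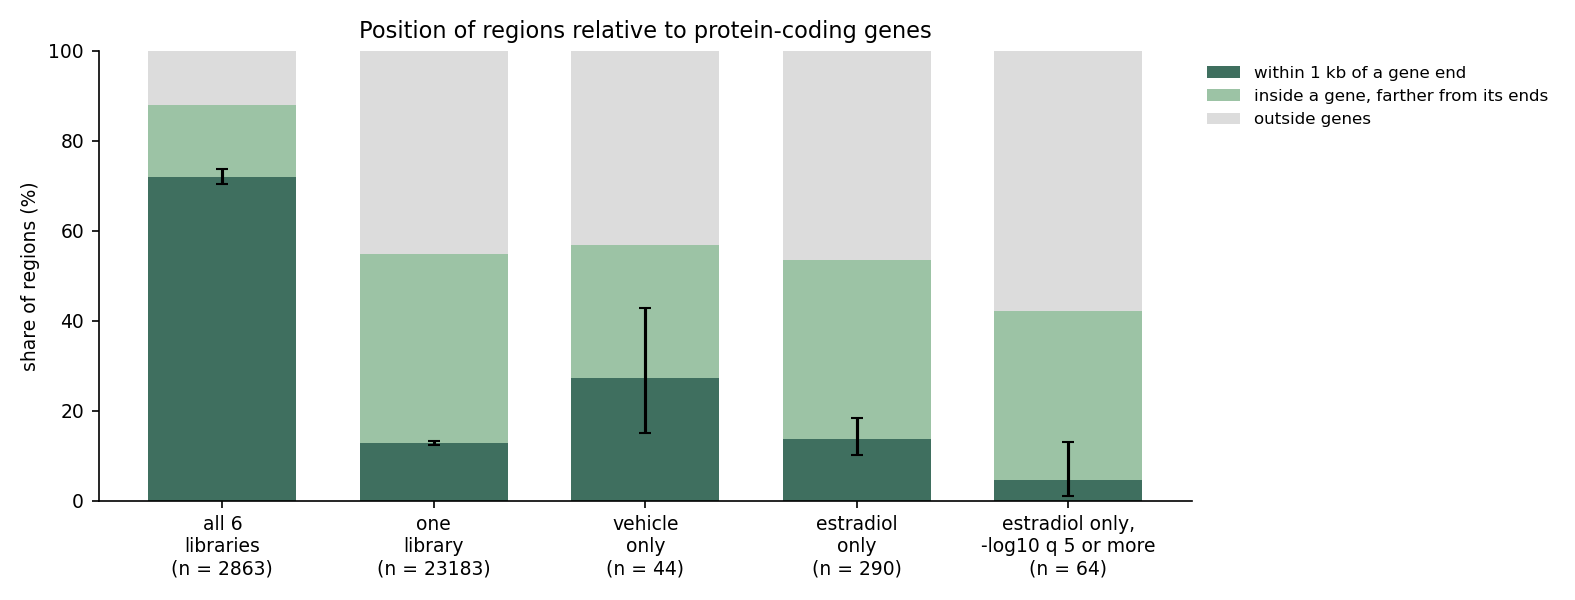
Share of merged regions (%) within 1 kb of a protein-coding gene end, inside a gene farther from its ends, or outside genes, by the libraries that hold them, with the number of regions under each bar. Black bars are exact 95% binomial intervals of the share near gene ends, which was 72.0% in all 6 libraries, 13.8% for estradiol-only regions and 4.69% for the 64 of these with −log10 q of at least 5.

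The number of peaks per library did not differ between the groups beyond the spread of replicates. Vehicle libraries held 13226 ± 7572 peaks (SD, n = 3) and estradiol libraries 14254 ± 3240 (SD, n = 3), a difference of 1028 (exact permutation p = 0.9, smallest possible 0.1). Within replicates 1 and 2 the estradiol mean was higher by 3034 peaks, and in replicate 3 the estradiol list was shorter (difference -2983). The difference turned to -2875 without vehicle replicate 1 and to -624 without estradiol replicate 3.

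**Figure D4:**
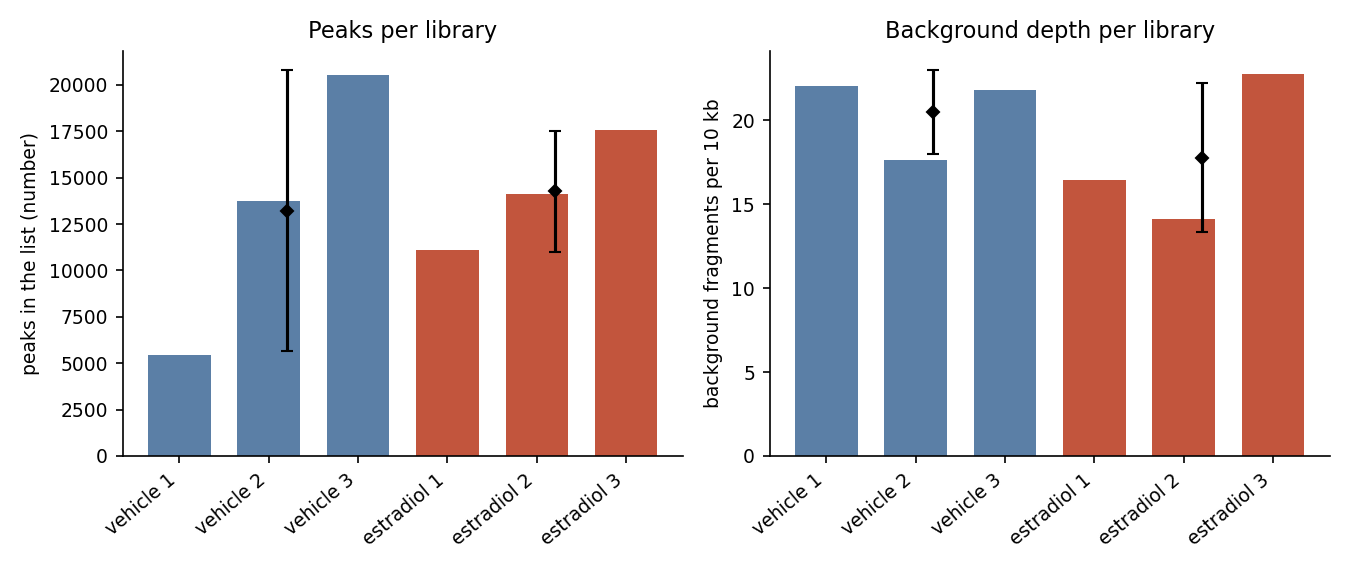
Peaks per deposited list (left, number) and estimated background fragments per 10 kb (right) in the 6 libraries, with diamonds and error bars for the group mean and SD (n = 3). Vehicle replicate 1 has the shortest list, 5421 peaks, with a background of 22.0 fragments per 10 kb.

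No closer resemblance was detected between lists of the same treatment than between lists of different treatments. The mean Jaccard index, the share of the regions of 2 lists that both hold, was 0.296 within groups and 0.299 between groups (difference -0.00260, exact permutation p = 0.9), and single pairs ranged from 0.182 to 0.359. The index is limited by unequal list lengths, and with lists of equal length it was 0.418 within and 0.412 between groups (exact permutation p = 0.7). The sign of the difference also turned without vehicle replicate 1, 2 or 3 (0.00385, 0.0189 and 0.0236). The lowest value was between vehicle replicates 1 and 3. Replicates 1 and 2 alone gave 0.244 for the vehicle pair and 0.349 for the estradiol pair, with 0.232 to 0.359 between groups, and replicate 3 has too few libraries for a value within groups.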

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

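The −log10 q thresholds of 5, 7 and 10 were chosen after seeing the data; the other settings were planned. The share of estradiol-only regions near gene ends stayed below that of regions in all the libraries used, with Fisher's exact p under 0.05, in each of 11 settings. It was 12.9% to 32.5% over them against 13.8%, highest without vehicle replicate 3 (32.5%), with 50% cover (30.6%) and with lists of equal length (27.4%). No gene list passed the random-list test with Benjamini-Hochberg adjustment in 5 other settings, with a smallest adjusted p of 0.105 to 0.357 over them and 1 to 3 lists with an unadjusted p under 0.05. The estradiol-only count was 113 with lists of equal length (5421 peaks), 1459 when 2 of 3 libraries sufficed, and 147 when peaks had to cover 50% of a region. The vehicle-only count was 42 with lists of equal length, 28 at the stricter threshold and 1024 when 2 of 3 libraries sufficed. Leaving out each library in turn gave 303 to 1003 estradiol-only and 78 to 876 vehicle-only regions, fewer libraries making the rule easier to meet. Estradiol-only counts over 1.5 times the full one were 653 without vehicle replicate 3, and 1003, 540 and 479 without estradiol replicate 1, 2 and 3. Vehicle-only counts were 876, 141 and 90 without vehicle replicate 1, 2 and 3, and 78, 99 and 136 without estradiol replicate 1, 2 and 3.

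At −log10 q of at least 5, 7 and 10 the estradiol-only counts were 64, 33 and 14, and each was also 64, 33 and 14 without vehicle replicate 1. Leaving out a vehicle library cannot lower an estradiol-only count, so these values alone do not show that the counts are stable. The vehicle-only counts were 1, 0 and 0, and 75, 10 and 0 without vehicle replicate 1. A higher threshold lowers a count by construction.

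The difference in peak number ranged from -2875 to 4685 over the left-out libraries, negative without vehicle replicate 1 (-2875) and without estradiol replicate 3 (-624). The within minus between difference of the Jaccard index was 0.00564 with lists of equal length and -0.0235 to 0.0236 over the left-out libraries, positive at 0.00385, 0.0189 and 0.0236 without vehicle replicate 1, 2 and 3. The cause was not tested.

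With the replicate number as a replicate block, 1943 regions had a peak in the estradiol and not in the vehicle library of the same number in at least 2 of 3 pairs and never the other way, and 1203 the reverse. Lists with the same number overlapped across groups by 0.0317 more in the Jaccard index than lists with different numbers, and the exact paired permutation test gave p = 0.75 for the peak number (difference 1028, smallest possible 0.25). The numbers were not taken to pair the libraries, because deviations correlated by -0.0293, 0.0213 and -0.0148 between libraries of the same number, and vehicle replicates 1 and 3 correlated best with another number.

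Not run were the estrogen response element shares, of estradiol-only regions and per library, with all their alternatives, because genome sequence was not used here. The low number of fragments per peak limits all of these results, since the median peak had 6 summit fragments in each library.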

Other observations

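The comparison with other splits of the libraries was planned, as was the list test for regions in at least 2 of 3 estradiol libraries. The other list tests, the thresholds of −log10 q, the counts of 2 libraries against 2, the ratios with lists of equal length, the background depth, the comparison of positions and the random regions were chosen after the results were seen. When 2 of 3 estradiol libraries and no vehicle library sufficed, 9 of 23 synaptic and ion channel genes had a region, against 4.23 from random lists (permutation p = 0.0147, adjusted p = 0.170). They included Cacna1c, a calcium channel, the glutamate receptor genes Gria1, Grin2a and Grin2b, and Gabra2, a GABA receptor subunit. Of the same list, 4 of 23 genes had a region in the reverse direction (2.28 from random lists), and Cntnap2, Grin2a and Shank2 had regions of both kinds. In all 6 libraries 7 of 23 had one (3.11 from random lists, permutation p = 0.0285, adjusted p = 0.121). Of 10 GABAergic neuron markers, 3 had a region in at least 2 of 3 estradiol libraries and no vehicle library (Dlx6, Meis2 and Six3; permutation p = 0.0200, adjusted p = 0.170). In the reverse direction 1 of 10 had a region (Slc32a1), and in all 6 libraries 2 of 10 (Dlx1 and Six3). Of 15 immediate early genes, 3 had a region in the estradiol direction (Fos, Fosb and Nr4a3, permutation p = 0.0719, adjusted p = 0.244) and 0 in the reverse direction (0.746 from random lists). In the reverse direction, 4 of 15 circadian clock genes had a region (Arntl, Cry1, Nr1d2 and Rora; permutation p = 0.00750, adjusted p = 0.127), and Rora also had one in the estradiol direction. None of the 17 lists passed after adjustment in either direction, and 3 and 1 had an unadjusted p under 0.05.

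Regions found in all 6 libraries were assigned to 6 of 15 immediate early genes (Egr1, Fos, Fosb, Ier2, Jun and Nr4a1) and to 6 of 15 clock genes (Arntl, Cry2, Dbp, Nr1d1, Per1 and Per3). Random lists gave 2.03 and 2.02 genes, and the adjusted permutation p was 0.0606 for both lists. No member of the ventromedial hypothalamic list (0 of 15, against 2.02 from random lists) had a region in all 6 libraries. The one-sided test asks only for an excess, so it cannot show a lack, and the lists were not compared with each other.

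A hypothesis was that estradiol-only regions gather at the same genes. They were assigned to 281 genes, and 14 genes had 2: 4930591A17Rik, Dpp6, Fgf12, Greb1, Grik1, Lrp1b, Med13l, Myo16, Myo3b, Myt1l, Pdzrn4, Pgr, Sez6l and Tecrl. Among 1000 random sets of other regions, equal in number and in share near gene ends, the mean was 6.24 genes (95% of sets 2 to 11.0), and the one-sided permutation p was 0.00599. Gathering of these regions around some genes may thus exceed that of such random sets, on the data in which it was noticed. The sets were not matched on peak strength or on the number of libraries holding a region. Whether the gathering is particular to estradiol-only regions therefore stays open.

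A second hypothesis concerned position. Of the 64 estradiol-only regions with −log10 q of at least 5, 3 (4.69%, 95% interval 0.977 to 13.1) lay within 1 kb of a gene end. In the 18 mixed sets of 3 libraries, 86 of 208 regions of that strength (41.3%, 34.6 to 48.4) did, with Fisher's exact p = 2.30e-09. Regions of that strength in a single library had a share of 18.2% (457 of 2510, Fisher's exact p = 0.00267). The strong estradiol-only share was 25.0% without vehicle replicate 3, 27.6% with lists of equal length and 14.3% with 50% cover. It was 10.1% without vehicle replicate 2 and 9.41% without estradiol replicate 3. In the first 3 of these settings the contrast with single-library regions was lost (20.3%, 28.9% and 23.0%; Fisher's exact p = 0.232, 0.828 and 0.149). The contrast with the mixed sets had a Fisher's exact p of at most 2.62e-06 with the stricter threshold, lists of equal length, 50% cover and each library left out in turn. Whether strong estradiol-only regions may form a class of distal sites stays open, and estrogen response element counts were not run here.

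The strong estradiol-only regions, 14 at −log10 q of at least 10, rest on a threshold chosen after seeing the data. Longer lists do not account for them, since among other sets of 3 libraries with at least as many peaks in all, the highest count was 1. Nor, at this threshold, does the weak vehicle replicate 1 account for the excess over vehicle-only regions. Without it, vehicle replicates 2 and 3 against any 2 estradiol libraries gave at most 3 such regions. The reverse counts were 14 to 44. They could not fall below 14, since the 14 regions meet the rule in every estradiol pair, so only the vehicle count was free to answer. At thresholds of 5 and 7 only 1 and 2 of the 3 estradiol pairs had more regions than the vehicle pair (lowest estradiol count 86 and 34, highest vehicle count 219 and 47), so vehicle replicate 1 may account for the excess at 5 and stays open at 7. Of the 10 splits the real one alone gave 14 and the highest other 1, but 10 splits are too few for a share under 0.05. Estradiol stays open as the biological explanation. By the rule that chose them, each of the 14 has peaks in the estradiol libraries of both batches and in no vehicle library of either. That pattern is therefore no evidence about a difference between batches. At this threshold replicates 1 and 2 gave 17 estradiol-only and 0 vehicle-only regions, while in replicate 3 vehicle-only regions were the more numerous. Replicate 3 has 1 library per group, so the contrast within that batch has no measure of spread.

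The excess of 290 estradiol-only over 44 vehicle-only regions may owe much to vehicle replicate 1. In counts of 2 libraries against 2, the ratio of mean estradiol-only to vehicle-only regions was 5.65 with it and 0.519 without it. List length alone is not shown to be the cause, since cutting every list to 5421 peaks left 113 against 42 regions, a ratio of 2.69 against 6.59. With those shorter lists the ratio of 2 against 2 was 1.71 with vehicle replicate 1 and 1.06 without it. Of the 10 sets of 3 libraries without vehicle replicate 1, 5 gave at least 290 regions, the real one included (the highest other 616). Of the 10 sets with it, 2 gave at least 44, the real one included (the highest other 52). Mixed sets thus exceeded both counts.

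Vehicle replicate 1 held 5421 peaks against 11082 to 20541 in the other libraries. Lower depth is an unlikely cause, as its estimated background of 22.0 fragments per 10 kb was the 2nd highest of the 6, above the median of 17.6 in the others. Its highest summit had 84 fragments, against 120 to 305 elsewhere, and 50.0% of its peaks lay near gene ends. A lower share of fragments in peaks remains open, whether from the tissue or from the assay, and no biological explanation was tested.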
